A study of Mus musculus with 33 samples.

How the data were processed

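Skin around the injection site was taken from mice 24 h after an intradermal injection of 1000000 Trypanosoma cruzi trypomastigotes, or of saline alone, in 100 µL over 2 adjacent sites, per the labels. RNA from each skin sample was hybridised to a 1-colour Affymetrix Mouse 430 2.0 array, and 33 arrays fall into 12 labelled groups. The deposited values are linear probe-set intensities, made by the submitters with RMA per the submitters' processing notes. The version of RMA and whether all arrays were normalized together are not given in the sources used here. The labels do not say that each array came from a separate mouse, so p-values measure the spread between these arrays, which may be partly technical.

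Each array held 45101 probe sets. The median intensity per array lay between 53.5 and 59.1 and the maximum between 24948 and 31832. No 2 arrays held identical values. The platform annotation listed 35890 probe sets with a gene, of which 34958 had exactly 1 gene and 932 had several; 9211 probe sets had no gene listed. The 64 control probe sets were left out. Of the probe sets with 1 gene, 34754 matched the reference table by gene number and 0 symbols changed. A gene with several probe sets was represented by the one with the highest mean over all 33 arrays, which gave 18193 genes. Values were analysed as log2 intensity with no further scaling and no filter on dim genes. The number of arrays limits the precision.

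All 33 arrays entered 1 linear model with a mean for each of the 12 groups. It was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 21 residual degrees of freedom). All groups, of 1 to 7 arrays, shared a common estimate of the spread of each gene. Tests were two-sided moderated tests, adjusted over all genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Every SE and adjusted p in the text comes from this limma model unless another setting is named. The 14 contrasts were each infected group against its own saline group, the infected Balb/c groups against each other, differences between responses (interactions), and each knockout saline group against its wild-type saline group. The NK-depleted pair had 1 array per group and no test. There, the median of a gene list was set beside the medians of 10000 random lists of the same size matched on mean expression, as a description of these 2 arrays.

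The lists of genes were 26, written before the data were examined, with 553 of 635 entries measured. They were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a contrast, and with fry, which tests whether a list moves on balance one way. The genes named for a contrast followed a rule also written before the data were examined. For infections and interactions the rule took the 8 called genes with the largest rise and the 5 with the largest fall (for infections, only genes that changed the same way in every infected array against the mean of the controls). It added up to 4 called members of each list (the 2 with the highest mean where none was called) and a fixed set of interferon and cytokine genes. For contrasts between infected groups and for baselines it took the 5 largest rises and the 5 largest falls. The text names fewer. Array-level values of H2-Ea, H2-Aa, Cd74 and Xist were added after the values were seen.

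The model was tested on simulated data with the real means and spreads of 18193 genes, 200 of them changed. For infection Y in Balb/c it recovered 89 of 100 genes changed by 1 and 99 of 100 changed by 2 on the log2 scale. For infection Y in 129 it recovered 85 and 98 of 100, and for the IFNARKO response difference 55 and 95 of 100. Of 17993 unchanged genes, 14 were called for infection Y in Balb/c (6.9% of calls) and 13 for infection Brazil (6.7%). For infection Y in 129 it was 13 (6.6%) and for the IFNARKO response difference 8 (5.1%). The simulated arrays varied independently around the overall mean of each gene. They lacked any structure between real arrays, so this does not show how the model fares on those.

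Alternatives were a fit on the compared groups only, an intensity trend with robust variances, array weights, leaving out genes under the median level, the mean of all probe sets per gene, every probe set on its own, a repeated quantile normalization, cyclic loess, a 2-fold minimum, the replicate number as a block, and leaving out each array in turn. One alternative was chosen after the data were examined. It left out the arrays whose H2-Ea level goes against the mouse strain in the label. For overlaps between responses that share control arrays, unchanged groups were simulated 100 times against 7 shared controls, and the 7 controls were also split into sets of 3 and 4 in all 35 ways. Arrays were kept in the groups their labels give, and no array was reassigned from its values. Of the arrays labelled Balb/c infected with the Brazil strain, 2 were analysed here.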

Results

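Gene expression in mouse skin was measured 24 h after intradermal injection of Trypanosoma cruzi, the parasite of Chagas disease, or of saline. The arrays carried the labels Balb/c saline (7 arrays), Balb/c with the Y strain (3), the Brazil strain (2) or the G strain (3) of the parasite, NK-cell-depleted saline (1) and Y (1), interferon-gamma knockout (IFNgKO, Balb/c background) saline (2) and Y (2), 129 saline (3) and Y (3), and interferon-alpha/beta receptor knockout (IFNARKO, 129 background) saline (3) and Y (3). Levels are log2 intensities, as mean ± SD over the arrays of a label.

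The labels were first set against genes that the mice should or should not express. H2-Ea, a class II gene silent in mice of the H2b haplotype such as 129 and expressed in H2d mice such as Balb/c, split the 33 arrays into 12 with levels from 4.29 to 5.11 and 21 with levels from 12.01 to 12.77 (probe set 1422892_s_at). The low set held 6 of the 7 arrays labelled Balb/c saline (replicates 1 to 6), the 3 labelled 129 Y and the 3 labelled IFNARKO saline. The high set held the 3 labelled 129 saline, the 3 labelled IFNARKO Y, and all 15 others. The level therefore went against the label in 12 arrays, 6 with a Balb/c label and 6 with a 129 or IFNARKO label. No association of label and level was detected over these 33 arrays (6 of 12 low against 6 of 21 low, two-sided Fisher's exact test p = 0.27). The test treats arrays as independent, but apart from Balb/c saline each labelled group lay wholly on a single side. It therefore does not show that the labels carry no information on mouse strain. A second H2-Ea probe set made the same split, with levels up to 8.33 in the low set and from 10.41 in the high set. In all, 36 probe sets of 28 genes separated the same 12 arrays from the same 21 by more than 1 on the log2 scale. For Pdxdc1, 1 probe set was higher in the high set (10.28 to 10.67 against 5.47 to 6.96) and another was lower there (5.81 to 6.59 against 9.05 to 10.04). Every direction given here is therefore a difference between arrays as labelled.

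**Figure D1:**
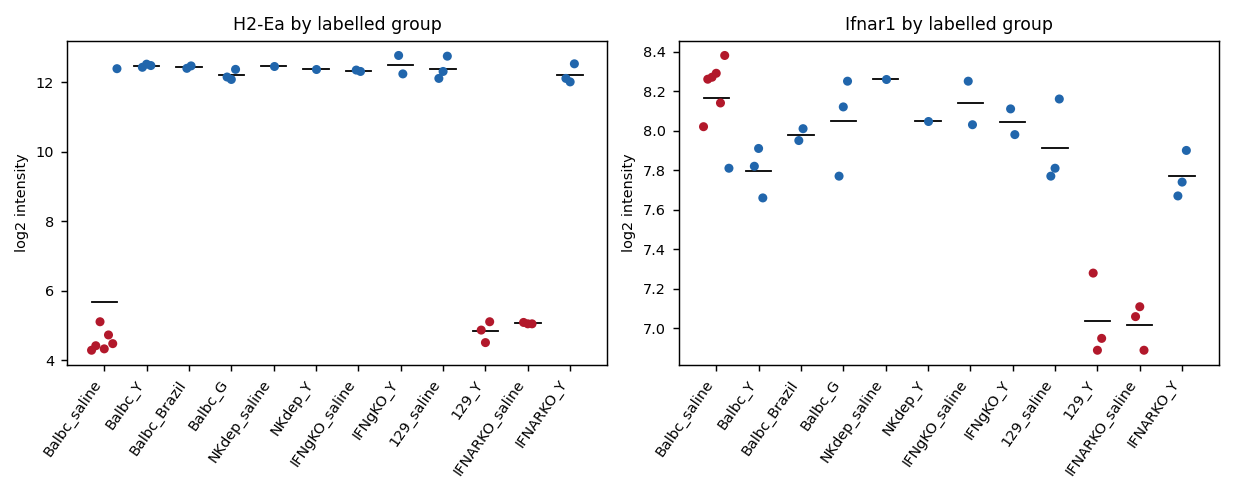
Log2 intensity of H2-Ea (left) and Ifnar1 (right) per array, by labelled group; each point is 1 array, the black line is the group mean, and red marks the 12 arrays with low H2-Ea. Of the 7 arrays labelled Balb/c saline, 6 have low H2-Ea, and Ifnar1 is lowest (6.89 to 7.28) in the arrays labelled 129 Y and IFNARKO saline.

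The genes targeted by the knockouts were read in every array. Ifnar1 (probe set 1449026_at) lay at 7.02 ± 0.12 (n = 3) in the arrays labelled IFNARKO saline and at 7.77 ± 0.12 (n = 3) in those labelled IFNARKO Y. It lay at 7.04 ± 0.21 (n = 3) in those labelled 129 Y and 7.91 ± 0.22 (n = 3) in those labelled 129 saline. The 6 arrays labelled 129 Y and IFNARKO saline ranged from 6.89 to 7.28, and the other 27 from 7.66 to 8.38. The probe's place relative to the disrupted part of the gene is not known here, so its level alone cannot check the label. Ifng (probe set 1425947_at) was near the floor in the arrays labelled IFNgKO, at 4.28 ± 0.21 (n = 2) for saline and 3.94 ± 0.15 (n = 2) for Y, and also in most others, so it does not check the IFNgKO label. It was highest in the arrays labelled Balb/c saline 4, 5 and 6, at 7.40, 6.21 and 6.47.

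The arrays also fell into 2 sets by their overall distribution. The upper quartile of intensity was 195 to 209 in the 9 arrays labelled Balb/c Y, 129 Y and IFNARKO saline, and 225 to 252 in the other 24. No labelled group had arrays in both sets, so wherever the groups compared lie in different sets, the set and the group cannot be told apart. The 8 contrasts that set the sets against each other had 1214 to 8328 genes called, and the other 6 had 0 to 2511.

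Interferon-response genes did not follow the saline and infection labels. The mean of 42 type I interferon-response genes was 10.71, 10.70 and 10.75 in the arrays labelled Balb/c saline 4, 5 and 6, against 7.48 to 7.99 in the other 4 saline arrays. Among infected labels it was 10.25 and 10.13 in Balb/c Y 2 and 3 but 8.01 in Balb/c Y 1. It was 10.27 and 9.77 in Balb/c G 1 and 2 but 8.24 in G 3, and 8.04 and 8.53 in the 2 Brazil arrays. In the IFNgKO arrays it was 10.31 and 7.76 for saline and 8.27 and 8.34 for Y. In the 129 arrays it was 8.71, 9.27 and 10.28 for saline and 6.86, 6.71 and 6.58 for Y. In the IFNARKO arrays it was 7.52, 7.08 and 7.50 for saline and 8.42, 10.76 and 10.84 for Y. The mean of 28 interferon-gamma-response genes exceeded that of the type I list by 1.22, 0.56 and 0.92 in the 3 arrays labelled IFNARKO saline. Only 1 other array, labelled Balb/c saline 2, had a difference above 0 (0.24).

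**Figure D2:**
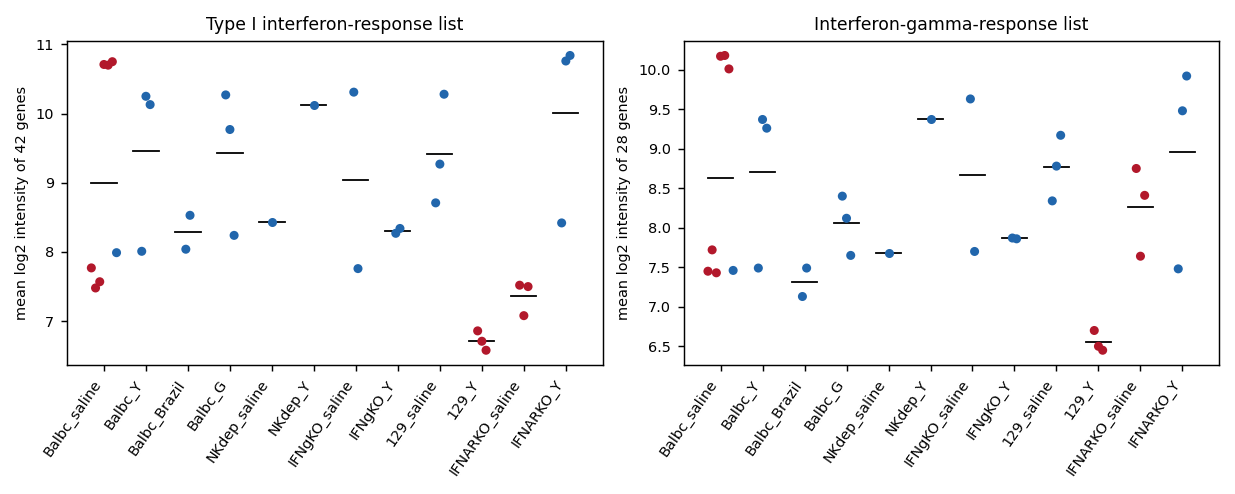
Mean log2 intensity of the type I interferon-response list (42 genes, left) and the interferon-gamma-response list (28 genes, right) per array, by labelled group; each point is 1 array, the black line is the group mean, and red marks arrays with low H2-Ea. The arrays labelled Balb/c saline lie at 2 levels, near 10.7 and under 8 for the type I list.

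Infection of Balb/c mice with the Y strain addressed the early skin response to the parasite. Comparing the 3 arrays labelled Balb/c Y with the 7 labelled Balb/c saline, Pdxdc1 rose by 3.90 (SE 0.62, adjusted p 9.2e-05), H2-Ea by 3.59 (SE 0.50) and Baiap2l1 by 3.38 (SE 0.57), and Serpinb11 fell by 3.47 (SE 0.52) and Gdpd3 by 3.31 (SE 0.47). These 5 are among 9 genes whose probe set in the model splits the arrays as H2-Ea does, and all 9 were among the 591 genes called with at least a 2-fold change. Pdxdc1 was not called on the mean of its probe sets (0.01). Outside that set, Krt18 rose by 3.18 (SE 0.72, adjusted p 0.0014) and Csn3 by 3.16 (SE 0.72, adjusted p 0.0015). Ltf rose by 2.63 (SE 0.27, adjusted p 6.5e-06), from 5.08 ± 0.19 (n = 7) to 7.72 ± 0.60 (n = 3). Krt18 and Csn3 were also higher in Y than in G (2.58 and 2.85). Both were lower in the IFNgKO response difference (-4.92 and -4.58). The source of this joint change was not tested. Dsc2 fell by 3.37 (SE 0.45, adjusted p 2.4e-05) and S100a8 by 1.99 (SE 0.50, adjusted p 0.0032). In the 1 saline array with high H2-Ea, Dsc2 was at 6.26, against 9.16 or more in the other 6. With those 6 left out its fall was 0.77 (log2 difference -0.77). In all 6946 genes were called, 2066 higher and 4880 lower; after a repeated quantile normalization 2250 were higher and 2838 lower. Of the 42 type I interferon-response genes 2 were called higher (1 when adjusted over the list alone), with a median of 0.43 (camera adjusted p 0.040, but 0.93 with the estimated correlation; fry 0.78). Of these 2, 1 also separated the arrays of low H2-Ea (up to 7.47) from those of high H2-Ea (from 7.84). The type I list spanned 7.48 to 10.75 among the 7 saline arrays. Of the proliferation genes 13 of 24 were called lower (13 adjusted over the list alone, median -0.57, camera adjusted p 0.0073, but 0.93 with the estimated correlation). The model without the arrays of conflicting H2-Ea left out all 12 of them, in other groups too. It kept 1 Balb/c saline array, so only differences are given from it here. Krt18 (2.88), Ltf (2.29) and S100a8 (-2.78) kept their direction. The median of the type I list was then 1.50. The arrays labelled Y and saline also lie in different sets by upper quartile.

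Between the arrays labelled Balb/c Brazil and those labelled Balb/c saline, Galc rose by 2.87 (SE 0.36, adjusted p 8.5e-05), from 5.06 ± 0.76 (n = 7) to 7.93 ± 0.58 (n = 2), and Spon1 rose by 2.89 (SE 0.44, adjusted p 0.00057). Dsc2 fell by 3.21 (SE 0.52, adjusted p 0.00082). Fitted on the compared groups only, Galc (adjusted p 0.056), Spon1 (0.064) and Dsc2 (0.084) lost their calls. So did Pdxdc1 (0.11), H2-Ea (0.12) and Cxcl9 (0.15), given below. Pdxdc1 (4.02, SE 0.72) and H2-Ea (3.13, SE 0.59) rose again, and 6 of the 13 most changed genes, Spon1 included, belonged to the set that splits as H2-Ea does. Cxcl9 fell by 4.44 (SE 1.17, adjusted p 0.017), a call lost without Brazil replicate 1 (-4.03) or replicate 2 (-4.84). In all 2052 genes were called, 1107 higher and 945 lower, and 331 without Brazil replicate 2. Interferon-gamma-response genes had a median of -1.14 (2 of 28 called lower, 1 adjusted over the list alone; camera adjusted p 0.0015, but 0.96 with the estimated correlation; fry 0.53), against a saline group in which the list mean ran from 7.43 to 10.18. Without the saline arrays of low H2-Ea the median was -0.07. Dsc2 then differed by -0.61, Galc by 1.22, Spon1 by 1.25 and Cxcl9 by -2.27.

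Between the arrays labelled Balb/c G and those labelled Balb/c saline, Lce3f rose by 2.47 (SE 0.38, adjusted p 0.00043), from 6.83 ± 0.67 (n = 7) to 9.29 ± 1.19 (n = 3). AY036118 fell by 2.33 (SE 0.24, adjusted p 1.3e-05) and Dsc2 fell by 2.79 (SE 0.45, adjusted p 0.0005), and Pdxdc1 (4.01, SE 0.62) and Baiap2l1 (3.47, SE 0.57) rose. Of the 13 most changed genes, 6 belonged to the set that splits as H2-Ea does. In all 2511 genes were called, 1290 higher and 1221 lower. The number was 4046 without saline replicate 7, and 1068, 1240 and 1461 without G replicates 1, 2 and 3. Of the epidermal stress genes 4 of 23 were called higher (6 higher and 1 lower adjusted over the list alone, median 0.52, camera adjusted p 0.037, but 0.85 with the estimated correlation). The type I list had a median of 0.36 (2 of 42 called higher, also adjusted over the list alone; camera adjusted p 0.20), and the 2 are the same genes as for Y. With the 6 saline arrays of low H2-Ea left out, that median was 1.48. Dsc2 then differed by -0.20, Lce3f by 1.33 and AY036118 by -2.47.

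The 3 responses in Balb/c mice shared their 7 control arrays. The Y and Brazil responses correlated across genes at r = 0.45, Y and G at 0.52, and Brazil and G at 0.75; genes are not independent replicates. Unchanged groups simulated against shared controls gave 0.26, 0.30 and 0.26. The covariances were 0.0816, 0.0873 and 0.112, against simulated 0.0129, 0.0128 and 0.0130. The simulation did not carry the structure of the real control arrays, which differed in H2-Ea. Their type I list mean also ran from 7.48 to 10.75. Simulated values may therefore understate what shared controls alone contribute, and the excess over them does not show a shared response. With disjoint sets of controls, over 35 splits, the mean r was 0.32 (0.11 to 0.50), 0.37 (0.20 to 0.53) and 0.56 (0.29 to 0.75). Brazil and G shared 477 genes called higher and 537 called lower, against 78 and 63 for independent lists, and 217 and 205 with disjoint controls. Y and G shared 189 and 791 (146 and 328 for independent lists; 62 and 410 with disjoint controls), and Y and Brazil 188 and 616 (126 and 253, and 70 and 356). Because 6 of the 7 controls had low H2-Ea and no infected Balb/c array did, disjoint sets of controls still share that difference.

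Direct comparison of the infected groups left the saline arrays out, and none of the arrays involved went against its label in H2-Ea. The Y arrays lie in the set of lower upper quartile and the Brazil and G arrays in the other, so differences of Y from both cannot be told apart from that of the sets. Against G, the arrays labelled Y had lower Cyp1a1 (7.28 ± 0.07 against 10.88 ± 0.11, n = 3 each; difference -3.60, SE 0.31, adjusted p 1.6e-07). They also had lower Krt6b (-4.08, SE 0.97, adjusted p 0.0037), Sprr1b (-4.00, SE 0.68, adjusted p 0.00021), S100a9 (-3.40, SE 0.61) and S100a8 (-2.85, SE 0.59). AY036118 (2.74, SE 0.28, adjusted p 1.6e-06) and Ntmt1 (2.82, SE 0.48) were higher in Y. Ntmt1 was also high in the arrays labelled IFNARKO saline (10.40), of the same set as Y, and low in those labelled IFNARKO Y (6.70). Of the epidermal stress genes 13 of 23 were called lower (15 adjusted over the list alone, median -0.91, camera adjusted p 0.00077, but 0.98 with the estimated correlation; fry 0.011), and of the proliferation genes 11 of 24 (13 adjusted over the list alone, median -0.59, camera adjusted p 0.00077, also 0.98 with the estimated correlation; fry 0.014). The type I interferon-response list was not called as different (median 0.03, 0 of 42 called, camera adjusted p 0.38). In all 4562 genes were called, 1518 higher and 3044 lower in Y; after a repeated quantile normalization 1460 were higher and 1213 lower. The number was 2829 without Y replicate 3 and 2939 without G replicate 2.

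Against Brazil, the arrays labelled Y had higher Ltf (7.72 ± 0.60, n = 3, against 5.14 ± 0.14, n = 2; difference 2.57, SE 0.36, adjusted p 6.9e-05) and Gm3715 (3.22, SE 0.57, adjusted p 0.00046), and lower Cyp1a1 (-3.31, SE 0.35, adjusted p 4.4e-06). Mucl1 was lower by 2.94 in Y (log2 difference -2.94, SE 0.61, adjusted p 0.0018), a call lost without Brazil replicate 2 (-2.03). Cxcl9 was higher by 3.96 (SE 1.33, adjusted p 0.036), a call lost without Y replicate 2 (3.49) or 3 (3.58) or Brazil replicate 1 (3.55) or 2 (4.36). The type I list had a median of 1.15 with 0 of 42 genes called (camera adjusted p 8.6e-05, but 0.99 with the estimated correlation; fry 0.63) and the interferon-gamma-response list 1.20 with 2 of 28 called, 1 adjusted over the list alone (camera adjusted p 8.6e-05, also 0.99 with the estimated correlation; fry 0.44). The model without the arrays of conflicting H2-Ea, none of them in this contrast, took its shared spread from fewer arrays. It called 7 of 42 type I genes higher, and 6 of 28 interferon-gamma-response genes higher and 1 lower, at the same medians. In the main model 3906 genes were called in all, 1183 higher and 2723 lower in Y, and cyclic loess gave 1315 and 1475. The number was 2414 without Y replicate 3 and 1893 without Brazil replicate 2. Between Brazil and G 10 genes were called, 8 higher in Brazil (3 of 5 after cyclic loess), among them Serpina6 (0.79, SE 0.14, adjusted p 0.039), with Hsd17b6 lower (-0.68, SE 0.13, adjusted p 0.041). That number went to 777 without Brazil replicate 1, to 0 without Brazil replicate 2, and to 1 and 2 without G replicates 2 and 3. Serpina6 was not called without Brazil replicate 2 (0.49) or any 1 of the G arrays (0.77 to 0.82), and Hsd17b6 not without Brazil replicate 2 (-0.66) or G replicate 2 (-0.67) or 3 (-0.57).

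**Figure D3:**
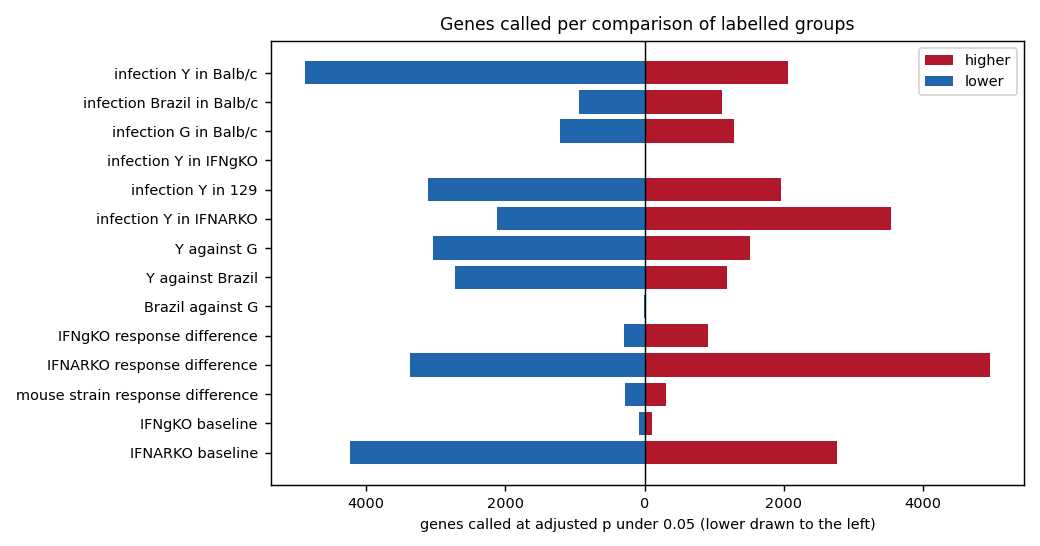
Number of genes called at an adjusted p under 0.05 in each comparison of labelled groups; bars to the right count genes that were higher and bars to the left genes that were lower. The largest number was 8328, for the difference between the IFNARKO and 129 responses, and infection Y in IFNgKO gave 0.

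The 129 arrays were compared as the wild type of the IFNARKO mice. Interferon-response genes were lower in the arrays labelled 129 Y than in those labelled 129 saline. Ifit1 was at 4.56 ± 0.22 against 10.57 ± 1.00 (n = 3 each; difference -6.01, SE 1.56, adjusted p 0.0075), and Oasl2 (-5.73, SE 1.29), Iigp1 (-5.69, SE 1.38), Gbp6 (-5.16, SE 1.25) and Cxcl9 (-4.25, SE 1.19, adjusted p 0.012) fell too. Ifnar1 fell by 0.87 (SE 0.15, adjusted p 0.0003), and Bcat2 (3.25, SE 0.38, adjusted p 8.2e-06) and Slc15a2 (3.21, SE 0.64) rose. Of the type I list 26 of 42 were called lower, 33 adjusted over the list alone (median -2.47, camera adjusted p 1.9e-08, but 0.78 with the estimated correlation; fry 0.11), and of the interferon-gamma list 14 of 28, with 16 lower and 2 higher adjusted over the list alone (median -1.64, camera adjusted p 0.0015, also 0.78 with the estimated correlation). Of the monocyte and macrophage markers 7 of 26 were called lower, also adjusted over the list alone (median -1.07, camera adjusted p 0.0016, also 0.78 with the estimated correlation). The arrays labelled 129 saline had high H2-Ea, against their label, and those labelled 129 Y had low H2-Ea, so no effect of infection is drawn from this. In all 5069 genes were called, 1957 higher and 3112 lower. The number was 3257 and 3017 without saline replicates 2 and 3 and 2982 without Y replicate 1, and cyclic loess gave 1463 higher and 1380 lower.

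In the IFNARKO arrays type I interferon-response genes were higher for Y than for saline. Ifi44l rose by 5.74 (SE 1.20, adjusted p 0.00089), from 4.95 ± 0.35 in those labelled saline to 10.69 ± 1.35 in those labelled Y (n = 3 each), Slfn4 by 4.84 (SE 1.18, adjusted p 0.0033) and Tnnt1 by 5.24 (SE 0.59, adjusted p 1.2e-06). Gm3715 fell by 4.84 (SE 0.51, adjusted p 6e-07). Ifnar1 itself rose by 0.75 (SE 0.15, adjusted p 0.00044). Ifit1 rose by 5.08 (SE 1.56, adjusted p 0.016), a call lost without saline replicate 2 (4.72) or Y replicate 2 (4.51) or 3 (4.47). Of the type I list 26 of 42 genes were called higher, 31 adjusted over the list alone (median 2.89, camera adjusted p 3.6e-06, but 0.85 with the estimated correlation; fry 0.054), and of monocyte and macrophage markers 14 of 26, 18 adjusted over the list alone (median 1.24, camera adjusted p 0.00036, also 0.85 with the estimated correlation). The arrays labelled IFNARKO Y had high H2-Ea, against their label. Of the interferon-gamma list, with 14 of 28 genes called lower in 129, 1 gene was called higher here and 1 lower, also adjusted over the list alone. Of the hair follicle genes 2 of 32 were called higher and 0 adjusted over the list alone (median 1.03, camera adjusted p 0.30). Their mean was 7.50, 7.06 and 5.85 in the arrays labelled IFNARKO Y and 5.32, 5.42 and 5.28 in those labelled saline. In all 5664 genes were called, 3542 higher and 2122 lower, and after a repeated quantile normalization 1920 higher and 2673 lower.

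The difference between the IFNARKO and 129 responses asked which changes depend on the receptor. It was positive for Ifit1 (11.09, SE 2.21, adjusted p 0.00031), Ifi44l (10.57, SE 1.69), Oasl2 (9.97, SE 1.82) and Ifnar1 (1.62, SE 0.21, adjusted p 1.7e-06), and negative for Gm3715 (-7.29, SE 0.71, adjusted p 6.7e-08) and Slc15a2 (-6.77, SE 0.90). Of the type I list 38 of 42 genes had a higher response under the IFNARKO labels, also adjusted over the list alone (median 5.38, camera adjusted p 1.5e-08, but 0.84 with the estimated correlation; fry 0.0083). Of the monocyte and macrophage markers 20 of 26 had a higher response, 22 adjusted over the list alone (median 2.41, camera adjusted p 0.00018, also 0.84 with the estimated correlation; fry 0.0083). Of the fibroblast and matrix genes 14 of 27 did, also adjusted over the list alone (median 1.11, camera adjusted p 0.025, also 0.84 with the estimated correlation). In all 8328 genes were called, 4963 higher and 3365 lower, and after a repeated quantile normalization 2772 higher and 3524 lower. A set of 109 genes chosen on other arrays, called up at least 2-fold in Balb/c Y, changed by a median of 0.70 in 129 and 0.04 in IFNARKO, with 33 genes lower and 30 higher in IFNARKO adjusted over the set alone. The median difference was -0.73. For a set of 128 genes chosen on the G response it was 1.40, with 3 lower and 72 higher. Infection Y in Balb/c, on which the 109 genes were chosen, crosses the upper-quartile sets as infection Y in 129 does. Infection Y in IFNARKO crosses them the opposite way. Both sets of genes were also chosen against the Balb/c saline arrays, 6 of 7 with low H2-Ea. Neither set therefore tests the receptor apart from these differences between arrays. At baseline, the arrays labelled IFNARKO saline had lower Ifnar1 (-0.89, SE 0.15, adjusted p 9.1e-05) and Slfn4 (-4.80, SE 1.18, adjusted p 0.0031) and higher Rnase2a (4.33, SE 0.91) and Bcat2 (3.65, SE 0.38, adjusted p 1.1e-06) than those labelled 129 saline. There 6996 genes were called, 2760 higher and 4236 lower, and cyclic loess gave 2117 and 1806. The arrays labelled 129 Y had Ifnar1 (7.04) about as low as those labelled IFNARKO saline (7.02). The arrays labelled 129 saline and IFNARKO Y had H2-Ea against their label. The response difference and the baseline also set groups from different upper-quartile sets against each other. No effect of the receptor is therefore drawn from them.

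The IFNgKO arrays asked whether the response needs interferon-gamma. In these arrays 0 genes were called by limma between Y and saline (n = 2 each), with 714 at an unadjusted p under 0.05. Cxcl9 lay at 8.01 ± 0.04 for Y and 9.12 ± 1.48 for saline (difference -1.11, SE 1.46), and Ifng differed by -0.34 (SE 0.83). The type I list had a median of -0.74 (0 of 42 called, also adjusted over the list alone; camera adjusted p 0.011, but 0.96 with the estimated correlation; fry 0.95). IFNgKO saline replicate 1 carried the list at 10.31 and replicate 2 at 7.76, and without saline replicate 2 the number called was 285. The response differed from that of Balb/c in 1214 genes, 917 higher and 297 lower, among them Ltf (-3.56, SE 0.48, adjusted p 0.0017), Panx3 (2.97, SE 0.45, adjusted p 0.0051) and Dsc2 (3.66, SE 0.79, adjusted p 0.019). The Balb/c saline arrays enter this difference with their conflict in H2-Ea. Without those of low H2-Ea, Ltf was at -3.22, Panx3 at 2.28 and Dsc2 at 1.07. The number of genes called, 1214 in the main model, also depended on single arrays. The number fell to 0 without IFNgKO saline replicate 1, where Ltf (-2.95), Panx3 (2.15) and Dsc2 (3.26) were not called, and was 3511 without replicate 2. It was 51 and 1 without IFNgKO Y replicates 1 and 2, where Dsc2 was also lost (3.81 and 3.52), Panx3 (2.46) only without replicate 2. It was 318, 536 and 258 without Balb/c Y replicates 1, 2 and 3, 745, 772 and 689 without Balb/c saline replicates 4, 5 and 6, and 3181 without replicate 7. After a repeated quantile normalization 127 were higher and 125 lower. A set of 119 genes chosen on the 129 arrays changed by a median of 0.24 in Balb/c and -0.07 in IFNgKO, with 5 lower and 13 higher in IFNgKO adjusted over the set alone. These numbers were 0 and 1 without IFNgKO saline replicate 1, 9 and 9 without replicate 2, 0 and 3 without IFNgKO Y replicate 1 and 1 and 2 without replicate 2. They were 1 and 7, 2 and 11, and 1 and 6 without Balb/c Y replicates 1, 2 and 3. Infection Y in 129, on which the 119 genes were chosen, crosses the upper-quartile sets as infection Y in Balb/c does. Infection Y in IFNgKO does not cross them. The arrays labelled 129 saline also had H2-Ea against their label. The set therefore does not test interferon-gamma apart from these differences between arrays.

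At baseline 195 genes differed between the arrays labelled IFNgKO saline and Balb/c saline, 113 higher and 82 lower. Pdxdc1 (4.05, SE 0.72, adjusted p 0.0096) and H2-Ea (2.83, SE 0.59, adjusted p 0.018) were higher and Gdpd3 was lower (-2.79, SE 0.54, adjusted p 0.013), all from the set that splits as H2-Ea does, as were 6 of the 10 most changed genes. Without the saline arrays of low H2-Ea, H2-Ea (-0.32) and Gdpd3 (0.21) turned and Pdxdc1 was at 0.05. On the mean of its probe sets Pdxdc1 was at -0.02. The calls were lost without IFNgKO saline replicate 1 (4.10, 2.68 and -2.63), which left 71 genes, and 597 were called without replicate 2. Without Balb/c saline replicates 1, 3, 4, 5 and 6 the number was 128, 126, 120, 126 and 117, and 659 without replicate 7. The 129 and Balb/c responses differed in 589 genes, 302 higher and 287 lower in 129, with Gdpd3 (5.86, SE 0.72, adjusted p 1.7e-05) and Bcat2 (4.99, SE 0.50) higher and Pdxdc1 (-7.64, SE 0.96) and Baiap2l1 (-7.22, SE 0.88) lower. Pdxdc1 turned to 0.67 on the mean of its probe sets. Of the 13 most changed genes 5 split as H2-Ea does, and the number was 994 without Balb/c saline replicate 7 and 389 without 129 saline replicate 2. The arrays labelled 129 saline and 6 of the 7 labelled Balb/c saline enter this difference with H2-Ea against their label.

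The NK-depleted pair had 1 array per label and no replicate check. The NK markers Ncr1 (5.11 in saline, 5.02 in Y) and Klrd1 (5.78 and 5.71) were compared with the arrays labelled Balb/c saline. Ncr1 lay within their range (5.00 to 5.71) and Klrd1 below it (5.87 to 7.51). Against the arrays labelled Balb/c Y, Ncr1 lay below the range (5.67 to 6.11) and Klrd1 within it (5.55 to 5.79), so these markers do not check the depletion. Gzma (5.43 and 7.23) and Gzmb (5.70 and 7.75) were higher in the Y array. Pgr was at 5.00 in saline and 9.86 in Y, above the arrays labelled Balb/c Y (up to 7.39) and Balb/c saline (up to 8.30). The Y array also had higher Cxcl10 (10.51 against 7.38), Iigp1 (12.72 against 9.33), Ccl12 (10.36 against 7.00) and Igtp (11.89 against 8.80). All 42 type I interferon-response genes were higher in it (median 1.66, above all 10000 random lists, percentile 100) and 27 of 28 interferon-gamma-response genes (median 1.89, percentile 100). Also at percentile 100 were MHC class I, chemokines, inflammatory cytokines, pathogen recognition, complement, neutrophil, monocyte and macrophage, and epidermal stress genes (medians 0.29 to 0.60). The type I list mean was 8.44 in the saline array and 10.12 in the Y array. Within the single label Balb/c Y it ran from 8.01 to 10.25. Skeletal muscle genes were lower (median -0.44, percentile 0), and NK cell markers stood at percentile 63.4 (median 0.08). Both arrays had H2-Ea on the side of their label. Xist was at 7.01 in the saline array and 11.96 in the Y array, and at 11.21 or above in the other 31 arrays. The sex of the mice was not given in the labels, and a difference in sex would enter every value of this pair.

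The median of all genes for the difference between the IFNARKO and 129 responses was 0.09, and -0.05 after a repeated quantile normalization and -0.02 after cyclic loess. For Y against G it went from -0.10 to 0 under both, and for infection Y in IFNARKO from 0.06 to -0.04 and -0.01. Over the 14 contrasts camera called 76 list tests at the preset correlation and 0 with an estimated correlation between genes.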

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

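The tests on H2-Aa, on the hair genes and on the keratinocyte genes were chosen after the result was seen, the test on Y-linked genes after Xist had been seen but before those genes were examined, and the test on H2-Ea after the interferon genes and Ifnar1 had been seen but before H2-Ea was examined. Outliers were sought in the 7 arrays labelled Balb/c saline over 62 genes and lists. For a gene chosen without regard to these arrays, chance gives about 1 in 20 such groups. The genes were those named in the text, many for large differences in contrasts that use these arrays, so 1 in 20 is no baseline here. There were 13 outliers, and 11 of them were in replicate 7. For Pdxdc1, H2-Ea, Baiap2l1, Serpinb11 and Gdpd3, which split the arrays as H2-Ea does, this restates that split in replicate 7. This array stood apart high in Pdxdc1 (10.48, the next 6.47), H2-Ea (10.92, the next 7.68), Baiap2l1 (11.53, the next 7.66), Galc (6.71, the next 5.27) and the interfollicular keratinocyte list (11.93, the next 11.67). It stood apart low in Serpinb11 (6.50, the next 9.79), Dsc2 (6.26, the next 9.16), Gdpd3 (7.86, the next 11.12), Slc15a2 (6.08, the next 8.57), Cyp1a1 (7.87, the next 8.59) and Mucl1 (5.84, the next 7.45). Gm3715 was high in replicate 3 (9.38, the next 7.97) and the hair follicle list in replicate 2 (10.13, the next 6.76).

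Interferon-response genes and Ifnar1 crossed the deposited labels. Mislabelled arrays would put some arrays on the wrong side of a gene that depends on mouse strain, and H2-Ea put 12 of 33 arrays there, 6 under Balb/c labels and 6 under 129 or IFNARKO labels, so partners for an exchange exist. The alternative that H2-Ea follows inflammation asks other class II genes to move as widely. The H2-Aa probe set in the model ranged over 1.90 and Cd74 over 1.66, but H2-Ea ranged over 8.48. Another H2-Aa probe set separated the same arrays as H2-Ea, in the opposite direction (higher where H2-Ea was low). Its range was not examined, so the range of H2-Aa given here holds for the probe set in the model only. Deposited columns that do not belong to their labels may therefore be the source of the crossing, and infection and knockout effects of the groups involved cannot be read from them. Which label belongs to which array was not inferred, and arrays with matching H2-Ea can also be out of place.

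Hair follicle and hair shaft genes were high in 2 arrays, labelled Balb/c saline 2 (list mean 10.13) and 129 Y 3 (11.40), against a median of 5.21 over the 33 arrays. Both arrays were the 2 highest in 30 of the 32 list genes, which shows that the difference was spread over the list but restates it and tests no source. Scaling of these arrays would move other abundant skin genes, but the interfollicular keratinocyte list lay at most 0.11 from the median array in them. Growing hair follicles in the sampled skin stay open as a possible explanation. Hair growth state was not given in the labels, and no biological explanation was tested.

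Xist was low in the NK-depleted saline array (7.01). A mouse of another sex would have Y-linked genes far above the other arrays. The mean of Kdm5d, Eif2s3y and Uty was 3.64 there, 0.46 below the highest of the other arrays (difference -0.46; the others 3.55 to 4.09). This met the bound set beforehand against another sex. These genes lay near the floor in all 33 arrays, so no array shows that their probe sets respond, and a difference in sex stays open.

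Responses differed between groups by a test of the difference itself in 1214 genes for IFNgKO against Balb/c, in 8328 for IFNARKO against 129 and in 589 for 129 against Balb/c. All 3 differences involve arrays whose H2-Ea level contradicts the label. Other splits of the same arrays set these numbers beside chance. For IFNARKO against 129, 1 of 100 splits, the real one, gave as many genes and the highest other gave 7743. That is the smallest share 100 splits can give. It makes a random split an unlikely source only if any array could stand in any group. The 7743 points to a structure of these arrays that other splits also catch. For 129 against Balb/c 6 of 100 splits gave as many, the highest 6096, so chance was not excluded, and a split with several times the real number again points to a structure of the arrays other than their labels. For infection Y in Balb/c 1 of 100 splits gave as many as the real 6946 (highest other 5633) and for infection G 1 of 100 gave as many as 2511 (highest other 2118). Under the same condition a random split is an unlikely source of these numbers. The difference between arrays that goes with H2-Ea or, for Y, with the upper quartile stays a possible source. Infection Y in 129 (5069), infection Y in IFNARKO (5664), Y against G (4562) and the IFNARKO baseline (6996) have 10 splits each, too few for a share under 0.05. The real split was the 1 highest in each, and the highest other gave 0.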

How the results depend on the processing

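One alternative, leaving out the arrays whose H2-Ea level goes against their label, was chosen after the data were examined. It cannot be made for infection Y in 129 or IFNARKO, the IFNARKO and mouse strain response differences or the IFNARKO baseline. It gave 0 genes for infection Y in Balb/c, 79 for Brazil, 0 for G, 0 for Brazil against G, 0 for the IFNgKO response difference and 0 for the IFNgKO baseline, with 1 Balb/c saline array left. That array is assumed to vary like the other groups. Y against G gave 5002 genes, 4184 shared with the 4562, and Y against Brazil 4524, 3616 shared with the 3906. No array of these contrasts was left out, so their log2 differences were unchanged and only the shared spread moved. Their overlap therefore does not test the conflict of labels. Reversed values were Pdxdc1 (-0.10) and Baiap2l1 (-0.19) for Y, H2-Ea (-0.02) for Brazil, Baiap2l1 (-0.11) for G, and H2-Ea (-0.32) and Gdpd3 (0.21) at the IFNgKO baseline. Leaving out arrays by H2-Ea moves H2-Ea and the genes that split with it by construction. On the mean of probe sets Pdxdc1 reversed for the mouse strain difference (0.67) and the IFNgKO baseline (-0.02), since its probe sets go opposite ways.

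For the other alternatives the cause was not tested, except where fewer or more genes, fewer arrays or a size limit make it plain. Fitting only the compared groups gave 61 genes for Brazil, 594 for G, 2491 for Y against Brazil, 0 for Brazil against G, 4 for the IFNgKO response difference and 1 for the IFNgKO baseline. Besides the genes named for Brazil, calls were lost there for Serpina6 and Hsd17b6 (Brazil against G) and for Panx3 and Dsc2 (IFNgKO response difference). Pdxdc1, H2-Ea and Gdpd3 lost theirs at the IFNgKO baseline. The intensity trend gave 27 for Brazil against G. Array weights gave 595 for Brazil, 4781 for G, 9656 for 129, 7555 for Y against G, 2602 for Y against Brazil, 0 for Brazil against G, 2352 for the IFNgKO and 2516 for the strain response difference, 47 for the IFNgKO and 11097 for the IFNARKO baseline. Without dim genes, fewer were tested, with 4286 for Y, 1033 for Brazil, 2932 for 129, 3339 for IFNARKO, 2667 for Y against G, 2278 for Y against Brazil, 0 for Brazil against G, 4479 for the IFNARKO response difference, 109 for the IFNgKO and 3848 for the IFNARKO baseline. Every probe set on its own gave 12365, 4679 and 5687 for Y, Brazil and G, 1 for IFNgKO, 8935 for 129, 9935 for IFNARKO, 7879 for Y against G, 6723 for Y against Brazil, 60 for Brazil against G, 15010 for the IFNARKO and 1225 for the strain response difference, 614 for the IFNgKO and 12306 for the IFNARKO baseline.

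A repeated quantile normalization gave 3059 for 129, 2673 for Y against G, 252 for the IFNgKO response difference and 4267 for the IFNARKO baseline. Cyclic loess gave 2843, 2665, 243 and 3923 for these, and 5 for Brazil against G. A 2-fold minimum gave 591, 277 and 258 for Y, Brazil and G, 536 for 129, 917 for IFNARKO, 345 for Y against G, 466 for Y against Brazil, 0 for Brazil against G, 468, 3600 and 390 for the IFNgKO, IFNARKO and strain response differences, and 67 and 704 for the IFNgKO and IFNARKO baselines. The replicate block gave 1057 for Brazil, 0 for Brazil against G and 926 for the strain response difference. Replicate numbers do not pair the arrays. Gene list tests went from 76 to 0 with the estimated correlation. The set chosen on other arrays for IFNARKO reversed to 1.401 when chosen on G and was -0.392 without dim genes (14 lower and 22 higher, against 33 and 30). The set for IFNgKO reversed to 0.004 when chosen on 129 or IFNARKO by adjusted p alone (5489 genes), which changed both the source and the fold limit. It moved to -0.65 without dim genes.

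Leaving out 1 array gave 4947 to 8108 genes for Y, 331 to 2969 for Brazil, 1068 to 4046 for G, 0 to 285 for IFNgKO, 2982 to 4244 for 129, 4153 to 5366 for IFNARKO, 2829 to 3715 for Y against G, 1893 to 3386 for Y against Brazil, 0 to 777 for Brazil against G, 0 to 3511, 7192 to 8178 and 389 to 994 for the IFNgKO, IFNARKO and strain response differences, and 71 to 659 and 5116 to 6189 for the baselines. The sets chosen on other arrays ranged from -0.966 to -0.535 for IFNARKO and from -0.476 to -0.132 for IFNgKO. Of the named genes, 566 results without 1 array kept direction and call and 26 lost the call.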

Other observations

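In the arrays labelled Balb/c Y, G and IFNgKO saline, interferon-response genes divided arrays of one label although H2-Ea lay on the side of each label. Ifit1 was at 7.49 in Balb/c Y 1 against 11.61 and 11.47 in Y 2 and 3, at 7.87 in G 3 against 11.69 and 11.05 in G 1 and 2, and at 11.40 and 6.93 in IFNgKO saline 1 and 2. H2-Ea therefore does not show which arrays of these groups carry their own label.

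Over the 31 arrays in groups of more than 1, 20 had their nearest array by correlation in their own labelled group. The hair genes Krt25 (11.74, 12.84) and Krt71 (11.65, 12.78) were at their highest in the arrays labelled Balb/c saline 2 and 129 Y 3, and Krt25 was also at 10.55, 9.40 and 7.18 in the 3 labelled IFNARKO Y and at 7.63 in Balb/c saline 7.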
